A study of Homo sapiens with 11 samples.

How the data were processed

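Total RNA of umbilical cord blood CD34+ cells was extracted with RNeasy columns and amplified in 2 rounds with the MessageAmp kit, per the labels. The probe set identifiers are those of an Affymetrix human array. The deposited values are linear, a single intensity for each probe set and array, for 22283 probe sets and 11 arrays, as the authors processed them. The software that summarised the probe sets and its settings are not given in the sources used here. From the values, the authors scaled the deposited intensity columns of sets C and D to a trimmed mean of 500 (2 percent trimmed from each tail) and left those of sets E and F at trimmed means of 123.2 to 203.1, so the sets formed 2 processing batches that each held all 3 times. The table has no detection calls, and between 19.3 and 39.6 percent of the values of an array were under 16.

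Set letters and times were taken from the titles, and the TGF-beta treatment of the 2 h and 4 h arrays from the source names. Nothing in the labels says that sets came from separate donors or cultures, so p-values measure only the spread between these arrays, which may be technical. The value 16, the power of 2 nearest to the 25th percentile of all values (12.6), was added before the log2 step, and fold changes are on that scale, which understates the change of low genes. Arrays were quantile normalized. Probe sets with a mean log2 value above the 40th percentile (5.59) were kept, apart from 68 control probe sets and 52 that name genes linked to donor sex, and the probe set with the highest mean stood for each gene. Of the probe sets 19071 had 1 gene symbol, 1043 had several and 2169 had none listed; 19059 symbols were updated through their gene identifier, and no gene was named from a probe set with several. This left 8182 genes. No column of the table was left out.

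Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with data.table version 1.17.8 for the tables), with time and set as terms, all 11 arrays in 1 fit and Benjamini-Hochberg adjustment over the genes of a comparison at a threshold of 0.05. The fit had 5 residual degrees of freedom. The set was used as a block because the titles give each set at several times. Arrays of 1 set deviated together: the 10 pairs of arrays of the same set had correlations of their deviations from the group means between 0.341 and 0.543, against at most 0.172 for arrays of different sets. No 2 arrays were duplicates, since the closest pair had a correlation of 0.984 and a median absolute log2 difference of 0.179.

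Gene lists and cell type markers, 31 in number, were written from textbook knowledge before the data were examined, as were the design, the rule for named genes and 17 of the alternatives. Of their 688 genes 495 were measured, 107 lay under the filter and 86 had no probe set of their own. The 30 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, which left 0 lists past the threshold in each comparison. The lists of other cell types were erythroid, megakaryocyte and platelet, neutrophil granule and granulocytic precursor, monocyte and macrophage, dendritic, mast cell and basophil, B-lineage, T and NK, and fibroblast and stromal markers; endothelial markers were too few. Named genes were the 10 largest rises and 10 largest falls that passed the test and went the same way in every set (5 and 5 for 4 h against 2 h), up to 4 called members of each list by smallest p, and a fixed group of genes known to respond to TGF-beta, of which 1 is not analysed here. ID2, ID3 at 4 h against 0 h and against 2 h, and other genes outside this rule were chosen after their values were seen.

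The ratio of 3 prime to 5 prime control probe sets was compared by an exact two-sided permutation of times within sets. The fit was tested on simulated data with the real arrays' set effects and spread, 50 changed genes of each size among 8182 and 10 runs per comparison. At 2 h against 0 h it recovered 36.6 percent of genes changed 1.5-fold and 89.6 percent of those changed 2-fold; at 4 h against 0 h 50.4 and 94.2 percent; and at 4 h against 2 h 33.6 and 90.2 percent. False calls made up 5.29, 4.81 and 4.89 percent of calls in these simulations. The simulated noise was independent between genes, so the share of false calls in the real data can differ. Alternatives changed the block, normalization, added constant, filter, choice of probe sets, arrays and variance model. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.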

Results

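Human CD34+ cells from umbilical cord blood, a population enriched in blood stem and progenitor cells, were profiled on oligonucleotide arrays at 0 h, 2 h and 4 h. The labels name a treatment with TGF-beta, a cytokine that signals through SMAD transcription factors, for every 2 h and 4 h array, and give each array a set letter and a time. There were 4 arrays at 0 h (sets C, D, E and F), 3 at 2 h (sets C, E and F) and 4 at 4 h (sets C, D, E and F). Each array gave an intensity for 22283 probe sets, and 8182 genes were tested after the filter on low values. The trimmed mean intensity was 500.2 on every array of sets C and D and lay between 123.2 and 203.1 in sets E and F. The small number of arrays limits the precision of every value. The labels name no arrays kept for 2 h or 4 h without TGF-beta, so treatment and time in culture moved together in each comparison.

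At 2 h against 0 h, SMAD6, SMAD7, SKIL, ID1 and ID3 were among the 10 largest rises. SMAD6 and SMAD7, which encode the inhibitory SMADs, rose by log2 changes of 3.81 ± 0.23 (SE) and 3.60 ± 0.31, or 14.1-fold and 12.2-fold, in 3 of 3 sets (limma adjusted p = 1.02e-04 and 8.14e-04). SKIL, a corepressor of SMAD proteins, rose 6.16-fold (log2 change 2.62 ± 0.36, limma adjusted p = 0.0146). ID1 and ID3, inhibitors of helix-loop-helix transcription factors, rose 4.57-fold (log2 change 2.19 ± 0.13) and 6.08-fold (2.60 ± 0.25). CDKN1C, which encodes the cell cycle inhibitor p57, rose 3.89-fold (log2 change 1.96 ± 0.17, limma adjusted p = 8.14e-04).

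The largest rise at 2 h was that of RGS1, a regulator of G protein signalling, at 36.3-fold (log2 change 5.18 ± 0.24, limma adjusted p = 4.01e-05). Further genes among the 10 largest rises were FGFR3, a fibroblast growth factor receptor, at 11.3-fold, TNFSF14, a cytokine of the tumour necrosis factor family, at 7.98-fold, ENC1 at 6.14-fold and RGS16, another regulator of G protein signalling, at 5.34-fold. The largest falls were those of PTX3, a secreted pattern recognition protein, which fell by 1.77 ± 0.24 on the log2 scale, and TNFSF10, the death receptor ligand TRAIL, which fell by 1.59 ± 0.19. DUSP6 and DUSP4, phosphatases that act on MAP kinases, fell by 1.33 ± 0.21 and 1.23 ± 0.22, and the cytokine gene IL1B fell by 1.28 ± 0.12. TM4SF1, the small nucleolar RNA SNORA21, the kinase gene PIM1, PLEK and SLA completed the 10 largest falls, with log2 changes from -1.13 to -0.99. All 20 genes moved the same way in 3 of 3 sets, because the rule for naming them required it. RGS1, SMAD6, SMAD7, FGFR3, TNFSF14, SKIL and ID3 had mean levels of 4.97, 4.44, 4.97, 4.69, 4.95, 5.11 and 5.52 (log2) at 0 h, below the 5.59 at which the filter was set, so the size of their folds depended on the constant added before the logarithm. With that constant at 4 the log2 changes of these genes, in the same order, were 6.04, 4.95, 4.41, 4.38, 3.69, 3.33 and 3.05, and with it at 64 they were 3.93, 2.37, 2.47, 2.25, 1.94, 1.63 and 1.796. The size and order of the falls depended on it too, since PTX3 and SNORA21 had 2 h means of 5.123 and 5.317. With the constant at 4 the log2 changes of PTX3, TNFSF10, IL1B and DUSP6 were -2.25, -1.79, -1.32 and -1.415. With it at 64 they were -1.03, -1.16, -1.14 and -1.09, and TNFSF10 had the largest fall of the 10.

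Among the gene lists fixed before the data were examined, TGF-beta/SMAD target genes had the smallest camera p at 2 h with the preset correlation. Of their 42 measured members 12 rose and 3 fell (16 upward and 4 downward when adjusted over the list alone), and the camera test gave an adjusted p of 3.10e-06, or adjusted p = 0.146 with an estimated correlation. Members that rose included ID2 (log2 change 1.59 ± 0.17), the transcription factor genes RUNX3 (1.16 ± 0.13) and KLF10 (1.07 ± 0.16), and the transcriptional repressor gene BHLHE40 (1.29 ± 0.19), and TNFSF10, ETS2 and DUSP4 were the 3 that fell. Of 10 Notch pathway genes 3 rose and none fell (4 upward when adjusted over the list alone): the Notch ligand gene JAG2 at 2.75-fold and the Notch effector genes HES1 at 2.47-fold and HEY1 at 1.85-fold, with an adjusted p of 9.95e-04 for the list, or adjusted p = 0.146 with an estimated correlation. HES1 was also a member of the list of TGF-beta/SMAD target genes. Of 26 immediate early and stress genes 2 rose, RGS1 and IER3 (2.29-fold), and DUSP6 fell (6 upward and 2 downward when adjusted over the list alone). The adjusted p of that list was 0.0234, or adjusted p = 0.192 with an estimated correlation. The median log2 changes of the 3 lists were 0.17, 0.21 and 0.12. Within sets E and F alone their adjusted p values were 8.41e-07, 0.00228 and 0.155. Sets C and D held a single 2 h array, too few for p values to be read, although that fit is counted among the alternatives. At the preset correlation the target genes passed in 21 of 22 alternatives (highest adjusted p 0.565), the Notch genes in 19 of 21 (0.149) and the immediate early and stress genes in 12 of 22 (0.598). The calls of the Notch and the immediate early lists ended in the fit with the 3 prime to 5 prime GAPDH ratio as a covariate, which gave these 2 highest values.

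Other lists held few calls at 2 h. SMURF2, a ubiquitin ligase that targets SMAD proteins, was the 1 of 22 TGF-beta pathway components that rose (2.07-fold, limma adjusted p = 0.0130). CDKN1C, also a member of the list of TGF-beta/SMAD target genes, was the 1 of 5 measured CDK inhibitors past the test, and CDKN1A had a log2 change of -0.07 ± 0.37 (limma adjusted p = 0.959). Among 25 stem and progenitor cell genes SOCS2, a feedback inhibitor of cytokine signalling, and the transcription factor gene TAL1 rose by log2 changes of 0.86 ± 0.13 and 0.74 ± 0.14, and MEIS1, a homeobox gene, fell by 0.63 ± 0.11. CCR7, a chemokine receptor gene counted among 15 dendritic cell markers, rose 2.19-fold, and DDIT4, a stress-induced inhibitor of mTOR signalling, rose 2.31-fold. JUNB and MYC did not pass the test, with log2 changes of 0.92 ± 0.33 (limma adjusted p = 0.302) and -0.40 ± 0.20 (limma adjusted p = 0.473). Some calls at 2 h were fragile: TAL1 passed in 4 of 21 alternatives, DUSP4 in 6 of 21, MEIS1 in 7 of 22, JAG2 in 8 of 22 and TM4SF1 in 10 of 21.

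In all, 90 of 8182 genes passed the limma test at 2 h, 66 that rose and 24 that fell, and 34 of the rises and 9 of the falls were over 2-fold. Without the set as a block 24 genes passed, 21 upward and 3 downward, all 24 of them among the 90. Within sets E and F alone 15 genes passed, and within sets C and D, where a single set held a 2 h array and the fit had 1 residual degree of freedom, 0 passed. With values as deposited 23 genes rose and 20 fell, on a scale where the median change of all genes was -0.20. The mean log2 ratio of the 3 prime to the 5 prime GAPDH control probe sets, a sign of RNA length, was higher at 2 h than at 0 h in 3 of 3 sets, by 0.29 ± 0.10 (SD; exact permutation p = 0.25, two-sided, the smallest that 3 sets allow), and 6 genes passed with that ratio as a covariate. In that fit the median size of the 90 changes went from 0.98 to 1.06 and their median SE from 0.144 to 0.262, with all 90 in the same direction.

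**Figure D1:**
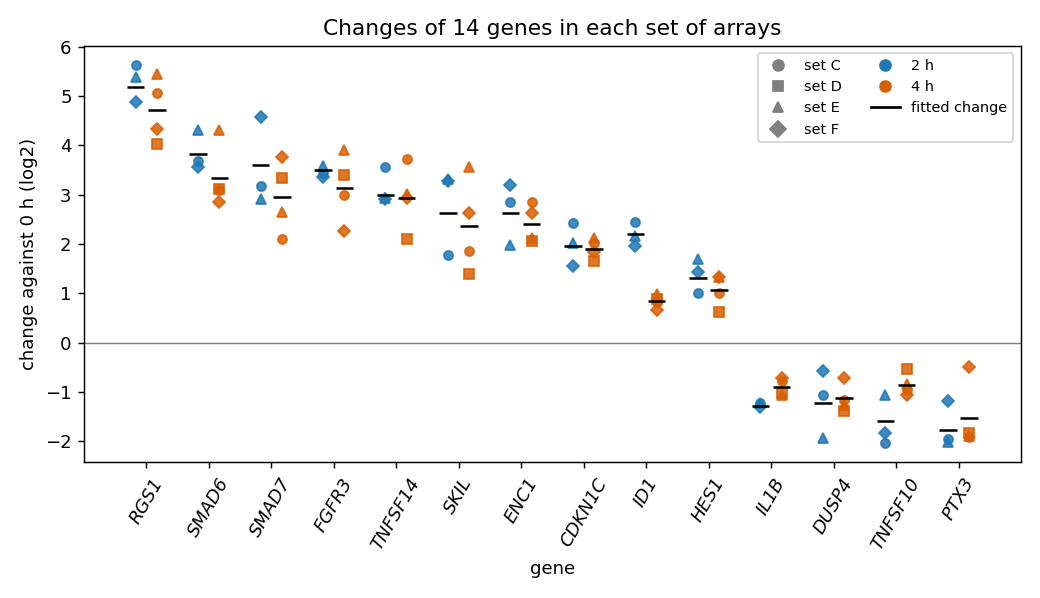
Change of 14 genes at 2 h (blue) and 4 h (orange) against 0 h, on the log2 scale, with 1 symbol per set of arrays and a black line at the fitted change. RGS1 stands highest, at 5.18 at 2 h and 4.71 at 4 h, and PTX3 lowest, at -1.77 and -1.54.

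At 4 h against 0 h, SMAD6, SMAD7 and SKIL were again among the 10 largest rises. SMAD6 and SMAD7 rose 10.1-fold (log2 change 3.34 ± 0.21, limma adjusted p = 1.86e-04) and 7.78-fold (2.96 ± 0.28, 0.00109) in 4 of 4 sets, and SKIL rose 5.11-fold (2.35 ± 0.33). RGS1 again had the largest rise, 26.2-fold (log2 change 4.71 ± 0.22, limma adjusted p = 3.44e-05). QPCT, which encodes glutaminyl cyclase, rose 6.95-fold, SERPINF1, a secreted inhibitor of blood vessel growth, 4.64-fold, and VASH1, another such inhibitor, 4.41-fold. FGFR3, TNFSF14 and ENC1 rose 8.79-fold, 7.67-fold and 5.32-fold. With the added constant at 4 and at 64 the log2 changes were 5.64 and 3.43 for RGS1, 4.45 and 1.98 for SMAD6, 3.83 and 1.85 for SMAD7, 4.02 and 1.94 for FGFR3, 3.65 and 1.88 for TNFSF14, and 2.99 and 1.44 for SKIL. CDKN1C rose 3.74-fold (log2 change 1.91 ± 0.15, limma adjusted p = 3.65e-04) and ID1 1.78-fold (0.83 ± 0.12, limma adjusted p = 0.00786).

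The 10 largest falls at 4 h were led by PTX3, which fell by 1.54 ± 0.22 on the log2 scale, SH3BP5, an adaptor that binds the kinase BTK, which was 2.64-fold lower, and VNN1, a pantetheinase, which fell by 1.38 ± 0.14. The transcription factor gene NFIB fell by 1.16 ± 0.14 and the mitophagy receptor gene BNIP3 by 1.13 ± 0.14. DUSP4, TM4SF1, FERMT1, PTGER3 and TIAM1, an activator of the GTPase Rac, followed with log2 changes from -1.13 to -1.07. The other probe sets of PTGER3 past the filter gave log2 changes of -0.21, 0.06 and -0.13, so its fall rested on 1 probe set. All of these falls, like the 10 largest rises, went the same way in 4 of 4 sets, because the rule for naming them required it. The 4 h means of PTX3, VNN1, NFIB and FERMT1 were 5.363, 5.04, 5.404 and 5.265 (log2), below the filter at 5.59. The size and order of these falls thus depended on the added constant. With that constant at 4 the log2 changes of PTX3, SH3BP5, VNN1 and NFIB were -1.92, -1.45, -1.88 and -1.49. With it at 64 they were -0.92, -1.23, -0.76 and -0.66, and SH3BP5 had the largest fall of the 10.

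TGF-beta/SMAD target genes were again higher as a list at 4 h. Of its 42 measured members 12 rose and 3 fell (16 upward and 5 downward when adjusted over the list alone), with a camera adjusted p of 1.92e-04, or adjusted p = 0.322 with an estimated correlation. Within sets C and D alone the adjusted p of the target genes was 0.0135 and within sets E and F alone 0.0013. At the preset correlation the target genes passed in 21 of 22 alternatives (highest adjusted p 0.397). TGFBI, an extracellular matrix protein gene (log2 change 0.78 ± 0.13), and TSC22D1 (0.67 ± 0.11) rose at this time, and ID3 had a log2 change of 1.06 ± 0.23 that missed the threshold (limma adjusted p = 0.0553). Of 22 TGF-beta pathway components SMURF2 rose 1.85-fold and SMAD3, which encodes a SMAD that carries the signal to the nucleus, fell by 0.76 ± 0.13 on the log2 scale. Of 10 Notch pathway genes JAG2 rose 3.31-fold and HES1 2.10-fold, and the list did not pass (adjusted p = 0.136).

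The lists of G1/S genes, of MYC targets and ribosome biogenesis, and of stem and progenitor cell genes were lower at 4 h, while G2/M genes (15 of 26 higher, adjusted p = 0.570) and cytosolic ribosomal proteins (18 of 27 higher, adjusted p = 0.683) did not pass. Of 30 G1/S genes 26 had a negative log2 change, none passed on its own (2 downward when adjusted over the list alone, CCND2 at -0.50 ± 0.11 and CCND3 at -0.38 ± 0.09, both D-type cyclin genes), and the camera adjusted p was 0.00968, or adjusted p = 0.322 with an estimated correlation. Of 28 MYC targets and ribosome biogenesis genes 1 fell (2 when adjusted over the list alone), MXI1, which encodes an antagonist of MYC, by 0.61 ± 0.10 on the log2 scale. That list had an adjusted p of 0.0158, or adjusted p = 0.322 with an estimated correlation. Of 25 stem and progenitor cell genes 3 fell and none rose (4 downward and 1 upward when adjusted over the list alone): the natriuretic peptide receptor gene NPR3 by 0.92 ± 0.12, the transcription factor gene HLF by 0.83 ± 0.16 and MLLT3, a regulator of stem cell maintenance, by 0.66 ± 0.11. Their list had an adjusted p of 0.0447, or adjusted p = 0.468 with an estimated correlation, and 0.0669 without the set as a block. The median log2 changes of the 3 lists were small, at -0.11, -0.12 and -0.15. Within sets C and D alone the G1/S, MYC and stem cell lists had adjusted p values of 0.0308, 0.0308 and 0.584, and within sets E and F alone 0.226, 0.255 and 0.0306. At the preset correlation they passed in 18, 19 and 12 of 22 alternatives, with highest adjusted p values of 0.226, 0.255 and 0.584. MYC itself had a log2 change of -0.71 ± 0.18, in 4 of 4 sets, that missed the threshold (limma adjusted p = 0.102).

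Genes of other lists changed in small numbers at 4 h. Among 17 apoptosis regulators BIRC2 and BCL2, which encode inhibitors of cell death, rose by log2 changes of 0.86 ± 0.12 and 0.57 ± 0.11, and TNFSF10 and FAS, a death ligand and a death receptor gene, fell by 0.85 ± 0.17 and 0.51 ± 0.11. As a list these regulators did not pass (8 higher and 9 lower, camera adjusted p = 0.632), with 2 upward and 5 downward when adjusted over the list alone. The other 2 probe sets of BCL2 past the filter did not both share its direction. The integrin gene ITGA4 fell by 0.81 ± 0.15, IL1B by 0.90 ± 0.11, and DUSP6 was 2.07-fold lower. CDKN1C was again the 1 of 5 CDK inhibitors that rose, and this list had an adjusted p of 0.0634 with the set as a block, or adjusted p = 0.623 with an estimated correlation, and 0.0332 without the block. Markers of other cell types gave 4 calls, CCR7 (2.67-fold higher), the mast cell and basophil genes HPGDS and CLC (which fell by 0.61 ± 0.13 and 0.53 ± 0.11) and CD36, which fell by 0.75 ± 0.13, and none of the 9 lists of other cell types passed the camera test. RUNX3 rose 1.99-fold, and JUNB and CDKN1A did not pass (limma adjusted p = 0.768 and 0.805). Fragile calls at 4 h were those of FAS (past the test in 3 of 21 alternatives), HPGDS and CLC (4 of 22 each), PTGER3 (5 of 21), BCL2 (8 of 22), TNFSF10, DUSP6 and HLF (9 of 22 each), CD36 (9 of 21) and FERMT1 (10 of 21).

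In all, 158 of 8182 genes passed the limma test at 4 h, 110 that rose and 48 that fell, with 42 rises and 13 falls over 2-fold. Without the set as a block 35 genes passed, 29 upward and 6 downward, all 35 among the 158. Within sets E and F alone 26 genes passed, and within sets C and D, with 1 residual degree of freedom, 0 passed. The mean changes of RGS1, SMAD6 and SMAD7 were 4.54, 3.11 and 2.71 in sets C and D and 4.89, 3.58 and 3.21 in sets E and F. Other named genes differed more between these pairs of sets. SKIL had 1.61 in sets C and D and 3.09 in sets E and F, and FERMT1 had -0.61 and -1.58. SERPINF1 changed more in sets C and D (2.66) than in sets E and F (1.77). With values as deposited 143 genes rose and 22 fell, with a median change of all genes of 0.11. The mean log2 GAPDH ratio was 0.03 ± 0.17 (SD) higher at 4 h, in 2 of 4 sets (exact permutation p = 0.875, two-sided), and the log2 ACTB ratio was 0.25 ± 0.24 higher, in 4 of 4 sets (exact permutation p = 0.125, the smallest that 4 sets allow).

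**Figure D2:**
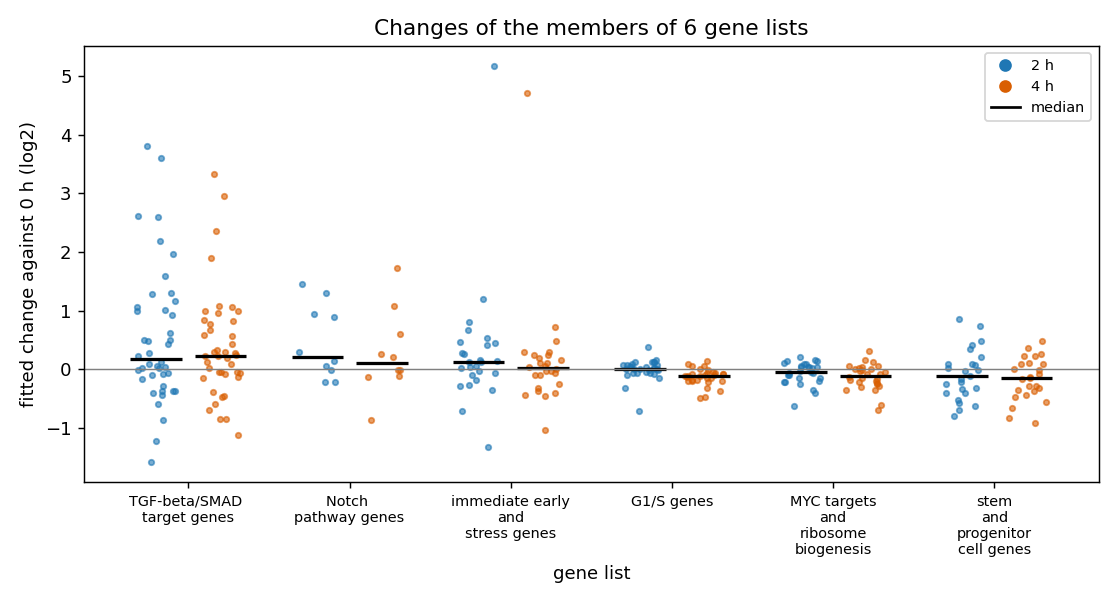
Fitted log2 changes of the members of 6 gene lists at 2 h (blue) and 4 h (orange) against 0 h, with 1 point per gene and a black line at the median. The TGF-beta/SMAD target genes have medians of 0.17 and 0.23, and the G1/S genes have medians of 0.01 and -0.11.

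The genes called at 2 h and at 4 h overlapped, with 56 genes called in both, all in the same direction. Of these 44 rose and 12 fell. They included SMAD6, SMAD7, SKIL, RGS1, CDKN1C, ID1, JAG2 and HES1 among the rises, and PTX3, DUSP4, DUSP6 and IL1B among the falls. Independent lists of the same lengths would share 0.887 rises and 0.141 falls. Both comparisons used the same 0 h arrays. The correlation of the 2 sets of log2 changes across genes, which are not independent replicates, was 0.637 against 0.450 for unchanged groups simulated against those arrays, and their covariance was 0.0515 against 0.0132. With no array in common the correlation across genes was between 0.318 and 0.342 and the covariance between 0.0337 and 0.0383. In those smaller fits 4, 15 and 5 genes were called at 2 h, 36, 0 and 0 at 4 h, and 4, 0 and 0 at both times. Where no gene was called at 4 h, none could be shared.

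At 4 h against 2 h, ID1 was lower and few other genes passed the test, which in simulated data recovered 33.6 percent of genes changed 1.5-fold. ID1 fell by 1.36 ± 0.13 on the log2 scale, or 2.57-fold, in 3 of 3 sets (limma adjusted p = 0.02). ARVCF, a catenin gene, fell by 0.91 ± 0.11, and ATXN1, a transcriptional regulator gene, rose by a log2 change of 0.97 ± 0.12, both in 3 of 3 sets (limma adjusted p = 0.0468 for each). The rule for the largest changes required the same direction in every set for these 3 genes. SMAD7, SKIL and CDKN1C had log2 changes of -0.64 ± 0.31, -0.27 ± 0.36 and -0.05 ± 0.17 and did not pass (limma adjusted p = 0.539, 0.841 and 0.941). The second probe set of ARVCF, which lay below the filter, gave a log2 change of -0.06. All 3 calls were fragile: ID1 passed in 6 of 20 alternatives (adjusted p from 0.00121 to 0.947), ATXN1 in 4 of 20 (0.0115 to 0.947) and ARVCF in 2 of 20 (0.00519 to 0.947).

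In all, 3 genes passed the limma test at 4 h against 2 h and 792 had an unadjusted p below 0.05. Without the set as a block ID1 alone passed. Within sets C and D alone and within sets E and F alone 0 genes passed, and leaving out any single set, C, D, E or F, also gave 0. The mean changes of ID1 were -1.63 in set C and -1.23 in sets E and F. ID2 and ID3 had log2 changes of -0.77 ± 0.17 (limma adjusted p = 0.259) and -1.55 ± 0.25 (limma adjusted p = 0.145), lower in 3 of 3 sets for each.

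**Figure D3:**
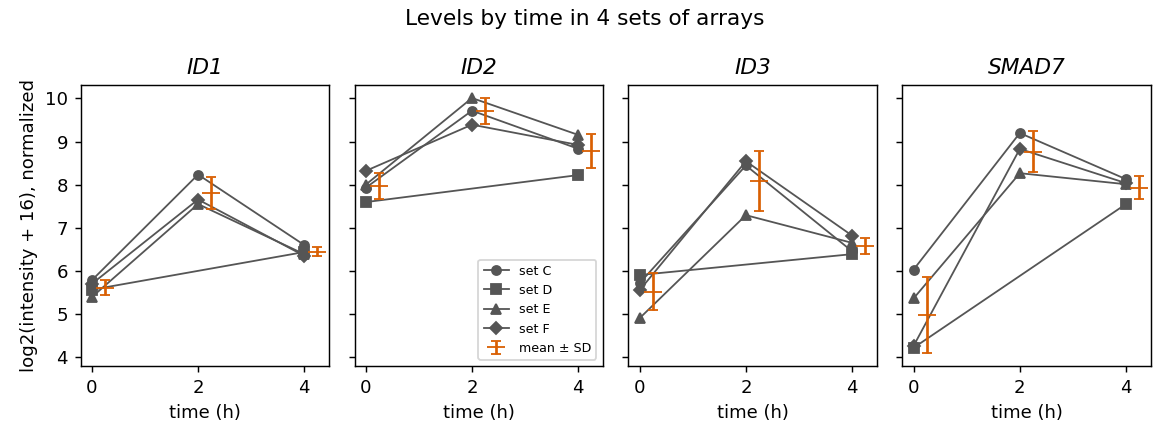
Normalized log2 intensity of ID1, ID2, ID3 and SMAD7 against time in hours, with 1 grey line per set of arrays and the mean ± SD in orange; set D has no 2 h array. ID1 had a mean of 5.61 at 0 h, 7.81 at 2 h and 6.45 at 4 h.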

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

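The tests of ribosomal RNA and cell types, of scaling on the genes changed against 0 h, of the missing 2 h array and of ID2 and ID3 were chosen after the results they measure had been seen, and the tests on ACTB were added after the GAPDH tests. The demand that a G1/S median pass its bound by more than the spread of the sets was also added after the values had been seen, as was a like demand on the cell type markers, and without the demand on G1/S the bound written before, -0.06, would have counted against scaling in sets E and F too. Of 66 groups of 4 values tested for a value far from the rest, 60 of them changes of named genes by set, 5 stood out, and chance gives about 1 in 20. PTX3 at 4 h fell by 0.50 in set F and by 1.83 to 1.92 in the other sets, a gap of 0.939 of the range. CDKN1A had a log2 change of 1.72 in set D and of -0.30 to -0.11 elsewhere, a gap of 0.909 of the range. CLC fell by 0.24 in set C and by 0.61 to 0.65 elsewhere (0.918 of the range), SMURF2 rose by 0.49 in set C and by at least 0.96 elsewhere (0.839), and TIAM1 fell by 1.35 in set C, while its smallest fall was 0.95 (0.865). Probe sets with several genes or no listed gene, outside the gene comparisons, gave 6 calls at 2 h and 17 at 4 h among 1582 tested.

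The genes that passed the test between the 2 later times were ID1 (log2 change -1.36 at 4 h against 2 h), ARVCF (-0.91) and ATXN1 (0.97). For the fall of ID1, the complete sets C, E and F gave -1.34, which decides nothing about the missing 2 h array of set D, since that set barely enters this comparison in a blocked fit. ID2 and ID3, read by other probe sets, were lower in 6 of 6 set values, which argues against a fault of the ID1 probe set alone. With the GAPDH ratio as a covariate the change of ID1 was -1.47 ± 0.23, against -1.36 ± 0.13 without it, so its size did not shrink, although the call ended (limma adjusted p = 0.552; 0.00121 to 0.947 over its 20 alternatives, 6 of them past the test) as the standard error grew. A change with time in culture stays open.

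For the genes changed against 0 h, the authors' unequal scaling is argued against for the 76 of 90 at 2 h and the 140 of 158 at 4 h that were also called with every array scaled to 500, and stays open for the other 14 and 18. Of the 100 genes with the smallest p in sets E and F, 76 went the same way in set C at 2 h and 92 in sets C and D at 4 h, against 56.9 and 59.1 percent of all genes. The 18S ribosomal RNA signal was 35.7 times the trimmed mean on the 0 h array of set D and 3.56 times on its 4 h partner. On the arrays of set E it was 41.6 times at 0 h, 37.2 times at 2 h and 39.55 times at 4 h. Of the 158 genes called at 4 h, 85 were also called without the 0 h array of set D. This argues against that array as their source, while the other 73 stay open because fewer arrays also end calls. A changed share of other cell types cannot be told apart: the largest median change of their 9 marker lists was -0.14 (monocyte and macrophage markers at 2 h), but the members went both ways and spread widely. Time in culture or handling without TGF-beta cannot be told apart from the treatment, because the labels name TGF-beta treatment for every 2 h and 4 h array and 0 untreated arrays at those times.

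For the G1/S genes lower at 4 h, RNA length is argued against by a median of -0.13 with the ACTB ratio as a covariate. That ratio was higher at 4 h in 4 of 4 sets. With the GAPDH ratio as a covariate the median was -0.12, which decides little, since that log2 ratio hardly differed between 4 h and 0 h (0.03 ± 0.17, SD). Only 0.08 percent of 10000 random lists matched on mean expression had a median as low. Genes drawn singly do not carry the correlation between G1/S genes, so this share does not allow for it. With an estimated correlation the camera adjusted p of the list was 0.322. The authors' unequal scaling is argued against in sets C and D, which were scaled alike and had a median of -0.11 (-0.14 in set C and -0.13 in set D). At the preset correlation the list passed in 18 of its 22 alternatives (highest adjusted p 0.226), the one with every array scaled to 500 among them. In sets E and F, with a median of -0.10, unequal scaling cannot be told apart, since set E alone gave -0.01 and set F -0.19.

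The count of 90 genes at 2 h was reached by 1 of 35 splits of the same arrays, the real one (highest other 1), the 158 genes at 4 h by 1 of 35 (highest other 1) and the 3 genes at 4 h against 2 h by 1 of 35 (highest other 1). The 3 lists at 2 h were reached by 2 of 35 splits (highest other 3) and the 4 lists at 4 h by 1 of 35 (highest other 2), and without the block by 16 and 12 of 35. Most of these splits part fewer pairs of a set than the real one and can call little with the set as a block. The 8 splits that part as many pairs are too few for a share under 0.05, and their highest others were 1, 0 and 1 genes and 2 and 1 lists. Without the block, 2 of 35 splits reached the 1 gene at 4 h against 2 h, and the split of sets E and F against sets C and D gave 160 genes, over the real 35 at 4 h, a structure of the arrays that follows the sets, in which scaling and other differences between sets were not separated.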

How the results depend on the processing

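The scalings to a trimmed mean of 500, the fits within 2 sets, the fit without the 0 h array of set D and the covariate were chosen after the data had been seen. No named value past the test was reversed in the 22 alternatives, and MYC at 4 h, not past the test in the reported fit, passed in 3 of them. The named values past the test went the same way in every set, by rule for the largest changes. Fits that leave out sets could therefore hardly reverse them. The fit in complete sets C, E and F and the fit without set D were the same, so tallies over alternatives count it under both names. Of the 79 named values past the threshold, 29 kept it without the block, 68 with set as a random block and 64 with a constant of 4. The cause was not tested. Genes near the floor at 0 h are limited by low signal, and between 19.3 and 39.6 percent of the values of an array were under 16.

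For genes at 2 h the counts were 24 with no block, 43 with values as deposited, 140 with a constant of 64, 27 with no filter, 151 with a filter at the 60th percentile, 51 without probe sets shared between transcripts, 15 with the 2 times alone, 165 with trend and robust, 0 in sets C and D, 15 in sets E and F, 6 with the covariate, and 16 (without E) to 69 (without D) leaving out a set. For genes at 4 h they were 35 with no block, 248 with a constant of 64, 103 with no filter, 93 without shared probe sets, 95 in complete sets, 268 with trend and robust, 0 in sets C and D, 26 in sets E and F, 93 without the 0 h array of set D, and 37 (without C) to 95 (without D). For genes at 4 h against 2 h they were 1 with no block, 9 with a random block, 0 with equal medians, 8 with a constant of 64, 0 with no filter, 1 with every probe set, 0 without shared probe sets, with the 2 times alone, in complete sets, with scaling to 500, in either pair of sets, without the 0 h array of set D and with the covariate, 9 with trend and robust, and 0 to 0 leaving out a set.

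The overlap was 15 with no block, 32 with values as deposited, 86 with a constant of 64, 20 with no filter, 89 with the 60th percentile, 33 without shared probe sets, 12 with the 2 times alone, 100 with trend and robust, 0 in sets C and D, 12 in sets E and F, 6 with the covariate, and 10 to 41 leaving out a set. Lists at 2 h numbered 0 without shared probe sets, 1 with the covariate, 0 with an estimated correlation, and 2 to 3 leaving out a set. Lists at 4 h numbered 0 without shared probe sets, 2 in sets E and F, 0 with an estimated correlation, and 1 (without C) to 4. At the preset correlation TGF-beta/SMAD target genes stayed past the threshold in 21 of 22 alternatives at both times. The exception was the one without shared probe sets, which leaves out the probe sets used for SMAD6, ID1, ID2 and ID3. With an estimated correlation this list did not pass at either time. The log2 3 prime to 5 prime ratio difference was 0.25 for ACTB at 4 h and 0.092 at 2 h, and for GAPDH leaving out a set gave -0.05 to 0.08 at 4 h and 0.24 to 0.34 at 2 h.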

Other observations

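The single genes of this paragraph lay outside the rule for named genes, were chosen after their values were seen, and were in no fixed list. LDLRAD4, which encodes an inhibitor of SMAD activation, rose at 2 h (log2 change 2.05 ± 0.12) and at 4 h (1.65 ± 0.11, limma adjusted p = 1.86e-04). VDR, the vitamin D receptor gene, rose 3.11-fold at 4 h, although 1 of its other 2 probe sets past the filter went the other way, and RXRA, its partner receptor gene, rose 1.49-fold with its other probe set going the other way. Other single genes that rose at 4 h were CX3CR1, a chemokine receptor gene, 3.21-fold (limma adjusted p = 0.00216, and 0.312 without the set as a block), MMP2, a gelatinase, 3.12-fold, AXL, a receptor kinase, 2.99-fold, CD9, a tetraspanin, 2.46-fold, and CDH1, which encodes E-cadherin, 2.15-fold. No list was fixed for them, and the fixed list of 22 adhesion and integrin genes had 0 rises and 1 fall at 4 h (limma camera adjusted p = 0.558). PTGER2, a prostaglandin E2 receptor gene, fell at 4 h by 0.93 ± 0.12 on the log2 scale, and HPGD, an enzyme that breaks down prostaglandins, fell by 0.89 ± 0.15. Without the set as a block LDLRAD4, VDR, MMP2 and PTGER2 still passed at 4 h, and RXRA, CX3CR1, AXL, CD9, CDH1 and HPGD did not.

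Some genes were called at 2 h alone. BCOR, a transcriptional corepressor gene, rose 2.83-fold at 2 h and had a log2 change of -0.02 ± 0.19 at 4 h, and HLX, a homeobox gene, fell by 0.96 ± 0.17 at 2 h and had a log2 change of -0.17 ± 0.15 at 4 h. The differences between 2 h and 4 h did not pass the test for these genes, so a transient response was not established. Gene lists at 4 h against 2 h were tested after the other results had been seen. The G1/S genes (27 of 30 lower, adjusted p = 0.00802), the immediate early and stress genes (0.0491) and the unfolded protein and amino acid response genes (0.0491) were lower, each with adjusted p = 0.261 with an estimated correlation.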
